A study of Mus musculus with 77 samples.

How the data were processed

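The series holds 77 files, 1 per library, and each was used as the authors deposited it: a table of read counts per Ensembl gene with no other column. The values were whole numbers and their totals differed between libraries, so no scaling was undone. Per the submitters' processing notes, cutadapt 1.13, STAR, HTSeq 0.6.1p1, DESeq2 and the mouse build mm10 were used; the notes give no version for STAR or DESeq2, no role for any tool, no annotation release and no strand setting for the counting. Per the labels' protocols, total RNA was extracted with Trizol and strand-specific mRNA libraries were sequenced on a NovaSeq instrument. Because the strand setting of the counting is not stated, counts of overlapping antisense genes are uncertain, as are counts of genes with near-identical copies such as Lilrb4a and the ribosomal protein genes. Counts were made on a mouse build, so transcripts of the human transgenes enter the counts of mouse genes such as App only as far as their reads align to them.

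The labels and file names divide the libraries into 2 sets. The 23 wild-type libraries of 9 weeks and the 24 libraries of day 24 are titled as merged, a word the labels do not explain, and their files list more genes than those of the 30 APPPS1-21 libraries of 9 weeks: 25006 genes were in both kinds of file and 29226 in the merged files alone, which held 0.748% to 2.52% of the counts of those libraries. At 9 weeks the genotype coincides with the library set, the depth and the gene list, so no main effect of genotype was tested at that age. Genes of the mitochondrial chromosome had a count of 0 in every library, so 33 of the 34 fixed gene lists could be tested. No pair of libraries of a group was a copy of another: over the 190 pairs, on genes with a summed count of at least 10, the lowest chi-square per degree of freedom was 3.01.

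Everything below was computed from those counts. Genes were kept by edgeR's filterByExpr by group (minimum count 10, minimum total count 15), scaled by TMM (factors between 0.958 and 1.05) and tested by edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3 with Benjamini-Hochberg adjustment over the genes of a comparison; an adjusted p under 0.05 was called. A group means model without covariates was fitted to each cohort: the 30 APPPS1-21 libraries of 9 weeks (5 groups, 16150 genes, common coefficient of variation 0.0977), the 23 wild-type libraries of 9 weeks (4 groups, 17736 genes, 0.106) and the 24 libraries of day 24 (4 groups, 17418 genes, 0.0869). Comparisons of age used the latter cohorts together (47 libraries, 8 groups, 18296 genes, 0.0967), and interactions with genotype at 9 weeks used both cohorts of that age (53 libraries, 9 groups, 16775 genes, 0.0997). Levels are CPM computed from these scaled library sizes; log2 CPM used a prior count of 2. Changes are log2 ratios with their standard error (SE).

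Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation and with fry; each list's genes were also adjusted over the list alone. A list score is the mean over a list's genes of log2 CPM centred on the cohort. Alternatives used DESeq2 1.42.0, limma voom with quality weights, 1 surrogate variable from sva 3.50.0, RLE scaling, no filter, and each comparison's own groups alone. Comparisons, lists, tests, these alternatives and the rule for named genes were fixed before the data were examined.

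Genes were named by a fixed rule. It took genes that check the labels, among them App, Thy1, Xist and Ddx3y where they bore on a comparison, and the 8 called genes with the largest change in each direction among those with an average of at least 1 log2 CPM. It took up to 4 members with the smallest p of each list that camera called and of the microglia, astrocyte, complement and immediate early lists. It took the 5 genes with the smallest p per direction where fewer than 10 were called, the 5 with the smallest p of an interaction, and a fixed panel of microglial and amyloid-related genes in the antibiotic and transfer comparisons. The text names some of the genes the rule selected, and Lilrb4a, which was chosen after its values were seen. Some genes the rule selected are not reported here. Ensembl identifiers and positions are those of GENCODE M21 on mm10, matched on the gene identifiers of the files.

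Simulated counts, drawn from the real means and library sizes with 50 genes changed at each of the log2 sizes 0.25, 0.5, 1 and 2, went through the same fit. For antibiotics in APPPS1-21 males 50%, 76%, 90% and 98% of these were called, in females 48%, 68%, 94% and 96%, and in the sex by antibiotic interaction 16%, 58%, 86% and 96%. The shares were 46%, 68%, 94% and 98% for transfer against antibiotics, 44%, 76%, 92% and 98% for transfer against vehicle, and 42%, 72%, 96% and 96% for the sex difference. For antibiotics in wild-type males of 9 weeks they were 24%, 62%, 82% and 100%, in females 32%, 68%, 86% and 96%, in their interaction 16%, 50%, 62% and 94%, and for the wild-type sex difference 28%, 60%, 82% and 98%. At day 24 they were 26%, 62%, 84% and 98% in wild-type and 32%, 66%, 90% and 100% in APPPS1-21 males, 10%, 36%, 76% and 98% for the interaction, 22%, 58%, 82% and 96% for genotype under vehicle and 30%, 64%, 86% and 98% under antibiotics. For age by antibiotic they were 14%, 62%, 70% and 90%, for the age difference 48%, 72%, 76% and 98%, and for genotype by antibiotic at 9 weeks 8%, 56%, 78% and 90% in males and 8%, 58%, 82% and 98% in females. The simulated genes varied independently of each other and without differences of tissue between libraries, so these shares do not cover such variation in the real data.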

Results

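RNA was measured by strand-specific mRNA sequencing in the dorsal cerebral cortex of the right hemisphere of mice. APPPS1-21 mice carry transgenes behind Thy1 promoter elements, among them human mutant amyloid precursor protein, and develop amyloid deposits; wild-type littermates were the controls. Mice received antibiotics (kanamycin, gentamicin, colistin, metronidazole and vancomycin) or vehicle by gavage from postnatal day 14 to 21, and tissue was taken at postnatal day 24 or at 9 weeks. A further group of APPPS1-21 males is labelled as antibiotics plus FMT, an abbreviation the labels do not expand, and is called the transfer group here. The 77 libraries form 13 groups of n = 6, except the vehicle-treated wild-type males of 9 weeks with n = 5. The 30 APPPS1-21 libraries of 9 weeks held between 51.9 and 59.8 M counts and the other 47 between 23.4 and 27 M. Within the first set the ranges were 53.7 to 57.3 (male vehicle), 54.3 to 58.4 (male antibiotic), 51.9 to 58.9 (male transfer), 55.6 to 59.8 (female vehicle) and 52.4 to 58.4 M (female antibiotic). Wild-type libraries of 9 weeks held 24.6 to 26.4 (male vehicle), 25 to 26.8 (male antibiotic), 25 to 26.7 (female vehicle) and 24.3 to 27 M (female antibiotic). At day 24, all males, the ranges were 24.3 to 26.2 (wild-type vehicle), 25.1 to 26.5 (wild-type antibiotic), 23.4 to 25.2 (APPPS1-21 vehicle) and 24.1 to 26.1 M (APPPS1-21 antibiotic).

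App and Thy1 transcripts stood higher in the APPPS1-21 groups than in wild-type mice of the same age. At 9 weeks App (ENSMUSG00000022892, chromosome 16, 84949685 to 85173766) stood between 2897 ± 105.2 (SD, n = 6; antibiotic-treated males) and 3647 ± 282.9 CPM (SD, n = 6; antibiotic-treated females) in APPPS1-21 groups. It stood between 1560 ± 80.62 (SD, n = 6) and 1654 ± 23.81 CPM (SD, n = 5) in wild-type groups. These 9-week levels compare library sets as well as genotypes. At day 24 Thy1, a neuronal surface glycoprotein, stood at 1355 ± 87.38 CPM in APPPS1-21 and 637.9 ± 16.53 CPM in wild-type vehicle-treated males (SD, n = 6 each). Xist, which silences an X chromosome in females, averaged 735.5 to 814.3 CPM in female groups and was at most 0.534 CPM in males, with an exception. The library labelled vehicle-treated APPPS1-21 male replicate 2 held 856.8 CPM of Xist and 0.138 CPM of the Y-linked Ddx3y, against 101.8 to 111.5 CPM of Ddx3y in the other libraries of its group. Its sex-linked transcripts were those of a female. It was kept, and values without it are given where they differ.

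Markers of tissue that borders the dorsal cortex varied between groups. The striatal neuron score averaged 1.06 ± 0.949 in antibiotic-treated wild-type males of 9 weeks (SD, n = 6) against -0.259 ± 0.407 in vehicle-treated ones (SD, n = 5). In APPPS1-21 males it averaged 0.0624 ± 0.46 (antibiotic), -0.248 ± 0.409 (vehicle) and -0.755 ± 0.355 (transfer; SD, n = 6 each), and in APPPS1-21 females 0.15 ± 0.48 (antibiotic) and 0.79 ± 0.3 (vehicle; SD, n = 6 each). The choroid plexus score averaged 0.862 ± 0.884, -0.285 ± 0.62 and -0.68 ± 0.448 in antibiotic, vehicle and transfer APPPS1-21 males (SD, n = 6 each). It averaged 0.62 ± 0.824 (SD, n = 6) against -0.652 ± 0.13 (SD, n = 5) in antibiotic- and vehicle-treated wild-type males of 9 weeks. These scores therefore moved with several of the groups compared below, though not all. In wild-type females of 9 weeks neither list passed under antibiotics. The median log2 change was -0.034 for striatal genes (camera adjusted p = 0.914) and -0.175 for choroid plexus genes (camera adjusted p = 0.569).

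**Figure D1:**
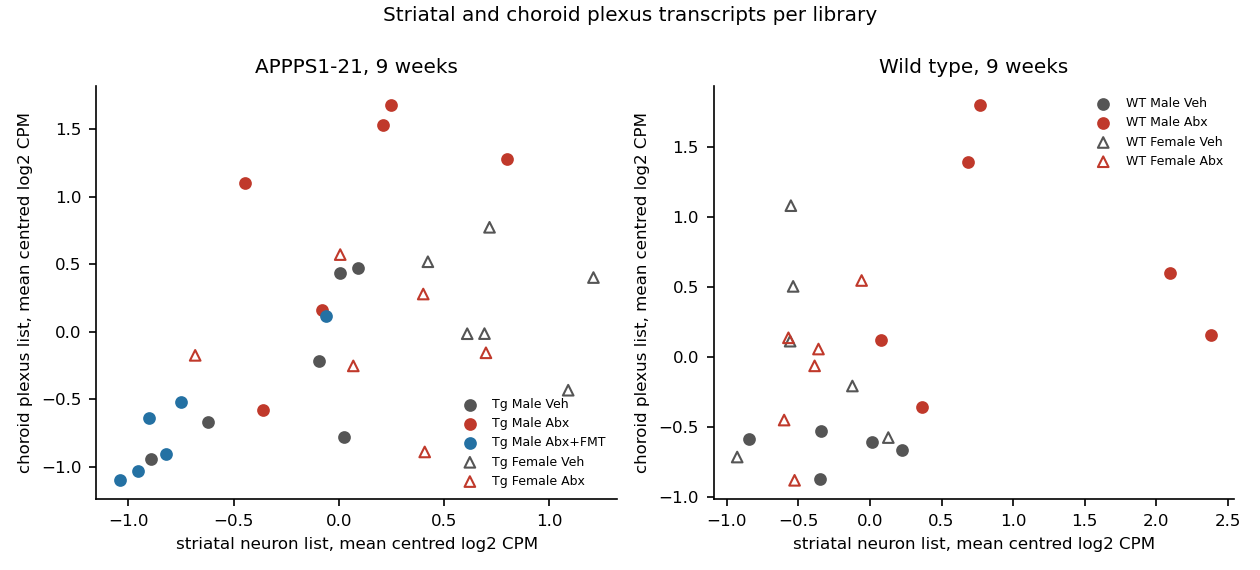
Choroid plexus score against striatal neuron score (mean centred log2 CPM) of each library of 9 weeks, with APPPS1-21 mice left, wild-type mice right, filled circles for males and open triangles for females. Antibiotic-treated wild-type males averaged 1.06 for striatal genes against -0.259 in vehicle-treated ones.

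The first question was what early antibiotics changed in the cortex of APPPS1-21 males at 9 weeks. Genes of activated microglia were among those that fell. Cst7 (ENSMUSG00000068129, chromosome 2, 150570415 to 150578944), a cystatin protease inhibitor, fell by 3.35 on the log2 scale (SE 0.533, adjusted p = 0.00616), from 1.95 ± 1.28 to 0.19 ± 0.117 CPM (SD, n = 6 each). Ccl3 (ENSMUSG00000000982, chromosome 11, 83647844 to 83649355) and Ccl6 (ENSMUSG00000018927, chromosome 11, 83587882 to 83593087), chemokines, fell by 2.44 (SE 0.389, adjusted p = 0.00616) and 1.40 (SE 0.237, adjusted p = 0.00771). With antibiotics Cst7 and Ccl3 (0.102 ± 0.0627 CPM, SD, n = 6) lay near the floor, so the sizes of their falls rest on few reads. Clec7a, the beta-glucan receptor dectin-1, fell by 2.39 (SE 0.438, adjusted p = 0.0182), from 1.62 ± 1.01 to 0.307 ± 0.118 CPM (SD, n = 6 each). Tyrobp, the adaptor through which Trem2 signals, fell by 0.55 (SE 0.109, adjusted p = 0.0351), and Lilrb4a, Cd180, Mpeg1 and Fcrls, all expressed by myeloid cells, fell by 2.003, 1.16, 0.43 and 0.42 (adjusted p = 0.0465, 0.0487, 0.0463 and 0.0463). The receptor Trem2 itself was at -0.45 (adjusted p = 0.0991), the integrin Itgax at -1.74 (0.0841), and markers of resting microglia at -0.19 (P2ry12, adjusted p = 0.356), -0.17 (Cx3cr1, 0.323), -0.05 (Csf1r, 0.743) and 0.07 (Tmem119, 0.796), none past the threshold.

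Of the 35 measured genes of the disease-associated microglia list, 6 fell and 0 rose over all genes, and 16 fell and 0 rose adjusted over the list alone. Camera gave adjusted p = 3.52e-13 (median log2 change -0.27), and adjusted p = 0.0446 with an estimated correlation. Of 29 homeostatic microglia genes 1 fell over all genes, and 5 fell and 1 rose adjusted over the list alone (adjusted p = 0.000688; adjusted p = 0.143 with an estimated correlation; median -0.12). Of 36 pan-microglial genes 1 fell, and 17 fell adjusted over the list alone (adjusted p = 8.74e-11; adjusted p = 0.143 with an estimated correlation). Interferon response genes were lower in 34 of 37 members, of which 0 were called over all genes or adjusted over the list alone (adjusted p = 3.43e-07; adjusted p = 0.333 with an estimated correlation). Of 19 complement genes 0 fell over all genes and 7 adjusted over the list alone (median -0.12, adjusted p = 0.00162; adjusted p = 0.284 with an estimated correlation). The 25 astrocyte markers did not pass (median 0.01, adjusted p = 0.311; adjusted p = 0.745 with an estimated correlation). Nor did 32 reactive astrocyte genes (median -0.06, adjusted p = 0.423; adjusted p = 0.783 with an estimated correlation) or 33 immediate early genes (median -0.02, adjusted p = 0.782; adjusted p = 0.935 with an estimated correlation). In these lists 0 genes were called either way. Without the library with female transcripts, camera for disease-associated microglia gave adjusted p = 1.64e-09, and adjusted p = 0.112 with an estimated correlation.

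App also fell in antibiotic-treated APPPS1-21 males, by 0.23 (SE 0.05, adjusted p = 0.0497), from 3390 ± 186 to 2900 ± 105 CPM (SD, n = 6 each). Thy1 was at -0.25 (SE 0.0735, adjusted p = 0.117). The App call held in 3 of the 12 fits that each left out a library and was lost without vehicle replicates 1, 2, 3, 4 or 6 or antibiotic replicates 2, 3, 4 or 5 (log2 change between -0.25 and -0.21). Genes that rose included Cpm, a carboxypeptidase (0.59, SE 0.101, adjusted p = 0.00771), and Daam2, a Wnt pathway formin (0.39, SE 0.0669, adjusted p = 0.00771). They also included Enpp2, which makes lysophosphatidic acid (0.35, adjusted p = 0.0351), and the folate receptor Folr1 of choroid plexus (2.06, SE 0.45, adjusted p = 0.0487). Of 29 choroid plexus and ependyma genes 3 rose over all genes and 24 adjusted over the list alone (median 1.18, adjusted p = 3.18e-17; adjusted p = 0.143 with an estimated correlation). Of 35 myelinating oligodendrocyte genes 1 rose and 16 adjusted over the list alone (median 0.25, adjusted p = 8.74e-11; adjusted p = 0.333 with an estimated correlation). The 25 striatal genes, of which 0 were called either way, had a median of 0.24 (adjusted p = 0.000402; adjusted p = 0.671 with an estimated correlation).

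In all, 10 genes rose and 20 fell of 16150, with 2268 at an unadjusted p under 0.05. Of the 20, Xist (-9.51) was called through the library with female transcripts and was at -0.43 (adjusted p = 0.677) without it. Its call was also lost without antibiotic replicates 2, 3, 4 or 5. The count moved by over 1.5 times without any library of the comparison except vehicle replicate 5, between 7 (without antibiotic replicate 3) and 159 (without antibiotic replicate 1). It was 94 without the library with female transcripts. The balance was not stable: DESeq2 called 152 higher and 93 lower, voom 653 and 330, the fit with 1 surrogate variable 157 and 89, and the comparison's groups alone 46 and 37. With the striatal and choroid plexus scores as covariates, an alternative chosen after the data were examined, 0 were called (Cst7 at -3.11, Clec7a at -2.17). Clec7a lost its call without antibiotic replicate 3 (-2.31, adjusted p = 0.056) and Tyrobp without vehicle replicate 3 or antibiotic replicates 3 or 5 (highest adjusted p = 0.103). Cst7 kept its call in all 12 fits (log2 change between -3.61 and -2.94).

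**Figure D2:**
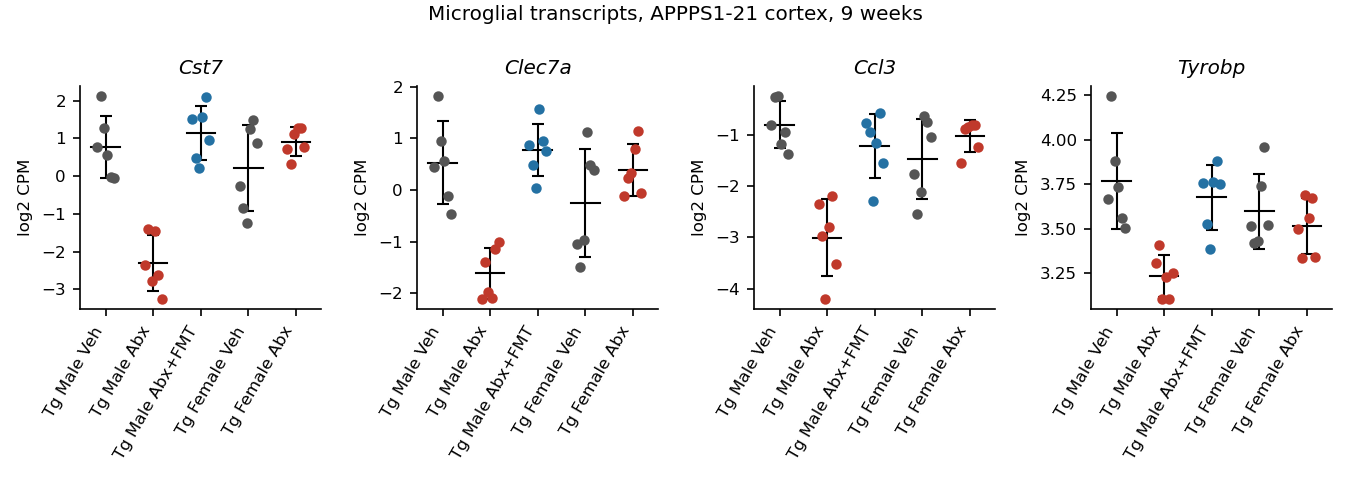
Log2 CPM of Cst7, Clec7a, Ccl3 and Tyrobp in each APPPS1-21 library of 9 weeks by group, with points for libraries and bars for mean and SD. Cst7 averaged 0.19 CPM in antibiotic-treated males, 1.95 in vehicle-treated males and 2.4 after transfer.

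In APPPS1-21 females antibiotics changed no gene past the threshold. The genes with the smallest p included Sqle, an enzyme of cholesterol synthesis, at 0.21 (87.6 ± 6.29 against 75.7 ± 4.98 CPM, SD, n = 6 each), and the striatal GTPase Rasd2 at -0.34. They also included the tryptophan-degrading enzyme Ido1 at -1.04, all with an adjusted p of 1. Cst7 was at 0.41 (SE 0.412), Clec7a at 0.41 (SE 0.385) and App at 0.02 (SE 0.05). The 25 striatal genes were all lower, 0 over all genes and 18 adjusted over the list alone (median -0.52, adjusted p = 1.39e-28; adjusted p = 0.136 with an estimated correlation). The 37 interferon response genes had a median of 0.16, with 35 higher and 0 called either way (adjusted p = 1.62e-09; adjusted p = 0.3 with an estimated correlation). The 74 nuclear oxidative phosphorylation genes had a median of -0.08 and 0 called either way (adjusted p = 3.72e-18; adjusted p = 0.253 with an estimated correlation). edgeR called 0 of 16150 genes, with 568 at an unadjusted p under 0.05; DESeq2 and voom also called 0.

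Whether males and females of APPPS1-21 responded differently was tested as an interaction, which called 3 genes, all of activated microglia. The male response minus the female one was -3.76 for Cst7 (SE 0.682), -2.79 for Ccl3 (SE 0.513) and -1.75 for Ccl6 (SE 0.328; adjusted p = 0.0462 for each). In females Cst7 stood at 1.9 ± 0.477 (antibiotic) and 1.43 ± 1 CPM (vehicle), Ccl3 at 0.465 ± 0.0963 and 0.367 ± 0.198 CPM and Ccl6 at 2.76 ± 0.683 and 2.16 ± 0.733 CPM (SD, n = 6 each). In males Ccl3 stood at 0.102 ± 0.0627 (antibiotic) and 0.563 ± 0.194 CPM (vehicle; SD, n = 6 each). Cst7 and Ccl3 lay near the floor in antibiotic-treated males, so the sizes of their interactions rest on few reads. The interaction of Clec7a was -2.80 (SE 0.585, adjusted p = 0.117), of Itgax -2.14 (adjusted p = 0.292) and of App -0.25 (SE 0.0707, adjusted p = 0.292). Of 35 disease-associated microglia genes 3 were lower in this sense, and 14 lower and 1 higher adjusted over the list alone (adjusted p = 1.62e-11; adjusted p = 0.0912 with an estimated correlation). Of 37 interferon genes 0 were called over all genes and 12 were lower adjusted over the list alone (median -0.39, adjusted p = 3.71e-14; adjusted p = 0.118 with an estimated correlation). Choroid plexus (22 of 29 higher adjusted over the list alone, median 1.39, adjusted p = 4.78e-19) and striatal genes (20 of 25, median 0.82, adjusted p = 1.7e-19) also differed. Both had 0 called over all genes and adjusted p = 0.118 with an estimated correlation. Of 16150 genes 1416 had an unadjusted p under 0.05, DESeq2 called 22 higher and 13 lower and the fit with the tissue scores 0. The calls needed nearly all libraries: 0 genes remained without any one of them, the library with female transcripts included. The exceptions were the 6 libraries named next. Without female vehicle replicate 4 there were 13, without male antibiotic replicate 4 there were 7 and without female antibiotic replicate 3 there was 1. Without female vehicle replicate 5 or male vehicle replicates 5 or 6 the count stayed within 1.5 times.

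Transfer after antibiotics was compared with antibiotics alone in APPPS1-21 males. Genes of activated microglia were among those that rose. Cst7 rose by 3.65 (SE 0.528, adjusted p = 0.00166), to 2.4 ± 1.17 CPM (SD, n = 6). Clec7a rose by 2.51 (SE 0.437, adjusted p = 0.00564), Ccl6 by 1.36 (SE 0.237, adjusted p = 0.00564) and Ccl3 by 2.04 (SE 0.401, adjusted p = 0.0111). The antibiotic levels of Cst7 and Ccl3 lay near the floor, as given above. Itgax rose by 1.94 (adjusted p = 0.0403), the pattern receptor Tlr2 by 0.94 (0.041), Mpeg1 by 0.44 (0.0142), Tyrobp by 0.45 (0.0453) and Fcrls by 0.37 (0.0472). App rose by 0.26 (SE 0.05, adjusted p = 0.00943), to 3470 ± 131 CPM (SD, n = 6). Of 35 disease-associated microglia genes 6 rose and 14 adjusted over the list alone (median 0.15, adjusted p = 2.57e-11; adjusted p = 0.0229 with an estimated correlation). Of 36 pan-microglial genes 1 rose and 11 adjusted over the list alone (median 0.19, adjusted p = 4.33e-14; adjusted p = 0.0229 with an estimated correlation). Of 37 interferon genes 0 rose over all genes and 14 adjusted over the list alone (median 0.33, adjusted p = 4.24e-16; adjusted p = 0.0593 with an estimated correlation).

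Genes of choroid plexus and myelin fell after transfer. The thyroid hormone carrier Ttr fell by 4.61 (adjusted p = 0.0489), the potassium channel subunit Kcne2 by 3.33 (0.00564), Folr1 by 3.05 (0.00402) and the tight junction gene Cldn2 by 3.16 (0.0106). Ndrg1, needed for myelin maintenance, fell by 0.50 (0.00166), and transferrin (Trf) by 0.54 (0.00738). The proliferation genes Mki67 and Top2a fell by 0.82 (adjusted p = 0.0297) and 0.83 (0.0415). Of 29 choroid plexus genes 16 fell and 24 adjusted over the list alone (median -1.57, adjusted p = 4.88e-33). Of 35 myelin genes 14 and 30 fell (median -0.43, adjusted p = 6.81e-43) and of 29 proliferation genes 3 and 6 (median -0.21, adjusted p = 6.44e-09), in the same order. Each of these lists had adjusted p = 0.0195 with an estimated correlation. Of 25 striatal genes 1 fell and 18 adjusted over the list alone (median -0.58, adjusted p = 1.68e-18; adjusted p = 0.0792 with an estimated correlation). In all 17 genes rose and 87 fell, with 1416 at an unadjusted p under 0.05. The count moved by over 1.5 times without antibiotic replicates 2, 3 or 5 or transfer replicates 1, 2, 3, 4 or 5, between 32 (without transfer replicate 1) and 218 (without transfer replicate 3). DESeq2 called 49 higher and 176 lower and voom 44 and 191, while the comparison's groups alone reversed the balance with 11 higher and 5 lower. The fit with the tissue scores called 0, with Cst7 at 3.2, Clec7a at 2.09, Ccl6 at 1.16, Tyrobp at 0.44 and App at 0.22 (adjusted p = 0.977 for each). Of the 12 fits that left out a library, Tyrobp kept its call in 1 (without transfer replicate 3) and Itgax in 3 (without transfer replicates 2 or 3 or antibiotic replicate 4). Cst7, Clec7a and App kept theirs in all 12.

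Transfer was also compared with vehicle. The activated microglial genes stood near the vehicle level: Cst7 at 0.30 (SE 0.398; 2.4 ± 1.17 against 1.95 ± 1.28 CPM, SD, n = 6 each), Clec7a at 0.13, Itgax at 0.20, Tyrobp at -0.10 (SE 0.107) and App at 0.04 (SE 0.05). None of these passed the threshold. The genes with the smallest p included the neurotensin receptor Ntsr1 (-0.44), Fam205c (0.33), the matrix protease Mmp2 (-0.49) and the phagocytosis receptor Mertk (0.34), with a lowest adjusted p of 0.306. The 35 myelin genes were all lower, with a median of -0.16 (adjusted p = 1e-14; adjusted p = 0.325 with an estimated correlation). The striatal genes had a median of -0.33 (adjusted p = 2.03e-07; adjusted p = 0.514 with an estimated correlation) and the choroid plexus genes of -0.30 (adjusted p = 0.00471; adjusted p = 0.632 with an estimated correlation). In these lists 0 genes were called over all genes or adjusted over the list alone. edgeR called 0 of 16150 genes, with 966 at an unadjusted p under 0.05, and DESeq2 and voom 0; without transfer replicate 3 there was 1.

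Of the 30 genes called under antibiotics, 29 had the opposite sign after transfer and 15 were called after transfer, all 15 in the opposite direction. Of the 20 lower genes, 9 rose past the threshold. Both comparisons share the antibiotic libraries, which makes their changes opposite by chance, so the antibiotic libraries were divided evenly between the comparisons in all 20 ordered ways. With the 500 genes of smallest p in the first comparison, a median of 83.2% (41.6% to 91.6%) had the opposite sign in the second, with a median slope of -0.47. Called genes could not decide this: 12 of the 20 splits had any (median 1), of which a median of 100% (44.4% to 100%) had the opposite sign. The splits with the most called genes showed no such majority. Of 714 called genes 44.4% had the opposite sign, and of 550 called genes 45.5%. The splits do not remove what the antibiotic libraries share as a group, such as their higher choroid plexus score. That alone can give opposite signs, so a return towards vehicle cannot be told apart from tissue in the dissection. The splits overlap, genes are not independent replicates and labels were not reassigned, so these shares have no chance level.

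**Figure D3:**
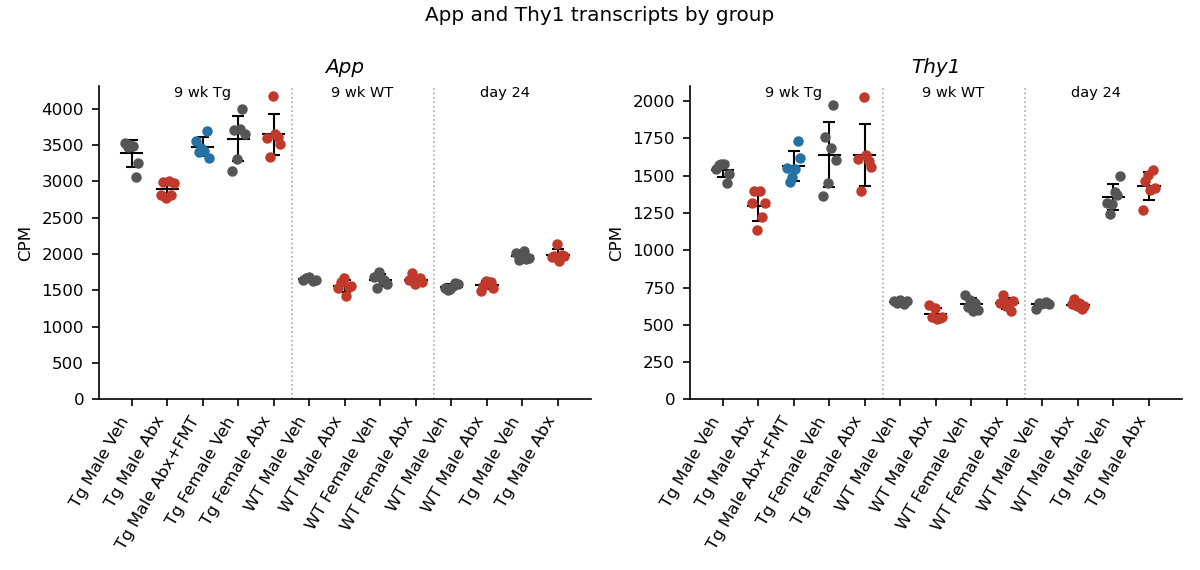
App and Thy1 levels (CPM) in each library by group, with points for libraries and bars for group mean and SD. App averaged 2897 CPM in antibiotic-treated APPPS1-21 males of 9 weeks, 3386 with vehicle and 3475 after transfer.

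Vehicle-treated APPPS1-21 males and females of 9 weeks differed in Y-linked genes such as Ddx3y (12.65, adjusted p = 1.06e-07) and in striatal and cholesterol genes. Rasd2 was lower in males by 0.70 (84.2 ± 7.28 against 137 ± 16.9 CPM, SD, n = 6 each; adjusted p = 3.82e-05). The dopamine receptor Drd2 was lower by 1.96 (3.6 ± 1.92 against 14 ± 4.8 CPM, SD, n = 6 each; adjusted p = 0.03). The cholesterol genes Sqle and Insig1 were higher in males by 0.26 (adjusted p = 0.00534) and 0.41 (0.0171). Of 25 striatal genes 16 were lower in males and 24 adjusted over the list alone (median -0.89, adjusted p = 1.15e-23; adjusted p = 0.271 with an estimated correlation). For these genes sex cannot be told apart from striatum in the dissection, and no fit with the tissue scores was made here. In vehicle-treated wild-type mice the striatal genes had a median of 0.13, higher in males (camera adjusted p = 0.0889, and 0.902 with an estimated correlation). Of 34 cholesterol genes 5 were higher, and 13 adjusted over the list alone (median 0.06, adjusted p = 0.00278; adjusted p = 0.532 with an estimated correlation). In all 152 genes were higher and 183 lower in males, with 3588 at an unadjusted p under 0.05. The count moved by over 1.5 times without female vehicle replicates 2, 4 or 5 or male vehicle replicates 1, 3, 4, 5 or 6, between 37 (without female replicate 5) and 786 (without female replicate 4). DESeq2 called 828 genes, and Xist did not pass (adjusted p = 0.225) through the library with female transcripts.

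In wild-type males of 9 weeks genes of neurons changed in both directions under antibiotics. The kinase Camk2a fell by 0.22 (3160 ± 209, n = 6, against 3680 ± 69.1 CPM, n = 5, SD; adjusted p = 0.00585) and the vesicle fusion protein Snap25 by 0.32 (3510 ± 543, n = 6, against 4370 ± 80.1 CPM, n = 5, SD; adjusted p = 0.00971). The exchange factor Rasgrf2 fell by 0.37 (0.00401) and the layer 4 transcription factor Rorb by 0.54 (0.00635). Of immature neuron genes, the sialyltransferase St8sia2 (0.89), Cd24a (0.71) and Marcksl1 (0.57) rose. Of striatal genes, Drd2 rose by 2.54 (SE 0.558, adjusted p = 0.0122), to 24.6 ± 21.7 (SD, n = 6) from 4.22 ± 2.15 CPM (SD, n = 5). The adenosine receptor Adora2a rose by 2.63 (0.0151), the phosphodiesterase Pde10a by 1.52 and the transcription factor Isl1 by 3.89 (0.0131). Ttr of choroid plexus rose by 4.35 (SE 1.27, adjusted p = 0.0369), to 166 ± 199 (SD, n = 6) from 8.2 ± 5.2 CPM (SD, n = 5). Thy1 fell by 0.20 (SE 0.0485, adjusted p = 0.0156), while App was at -0.08 (0.158), Trem2 at -0.25 (0.0855) and Tyrobp at -0.23 (0.191). Of 28 disease-associated microglia genes 4 fell and 1 rose, both over all genes and adjusted over the list alone. Their median was -0.05 (camera adjusted p = 0.0585, and 0.45 with an estimated correlation).

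Of 25 striatal genes 20 rose and 23 adjusted over the list alone (median 1.56, adjusted p = 1.69e-13), and of 28 choroid plexus genes 12 and 20 (median 1.54, adjusted p = 2.53e-09). Of 25 neuronal immaturity genes 10 rose, and 13 rose and 1 fell adjusted over the list alone (median 0.25, adjusted p = 6.62e-07). Of 74 nuclear oxidative phosphorylation genes, such as Ndufa9 (-0.21, adjusted p = 0.00788), 16 fell and 30 adjusted over the list alone (median -0.10, adjusted p = 4.54e-10). Of 24 excitatory neuron genes 6 fell and 1 rose, and 10 fell and 3 rose adjusted over the list alone (median -0.19, adjusted p = 0.0012). Each of these lists had an adjusted p of 0.414 with an estimated correlation. Of 34 cholesterol genes 5 fell and 7 adjusted over the list alone (median -0.12, adjusted p = 0.000198). Of 45 synaptic genes 11 fell, and 15 fell and 1 rose adjusted over the list alone (median -0.03, adjusted p = 0.00529). Both had adjusted p = 0.45 with an estimated correlation. In all 899 genes rose and 886 fell of 17736, with 4742 at an unadjusted p under 0.05. The count moved by over 1.5 times without vehicle replicates 1, 2, 4 or 5 or antibiotic replicates 4 or 6, between 758 (without antibiotic replicate 6, which had the highest striatal score, 2.38) and 2671 (without antibiotic replicate 3). It was 1074 without the 2 antibiotic libraries with the highest striatal scores, 35 with the comparison's groups alone (24 higher, 11 lower), 772 with 1 surrogate variable and 0 with the tissue scores as covariates.

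**Figure D4:**
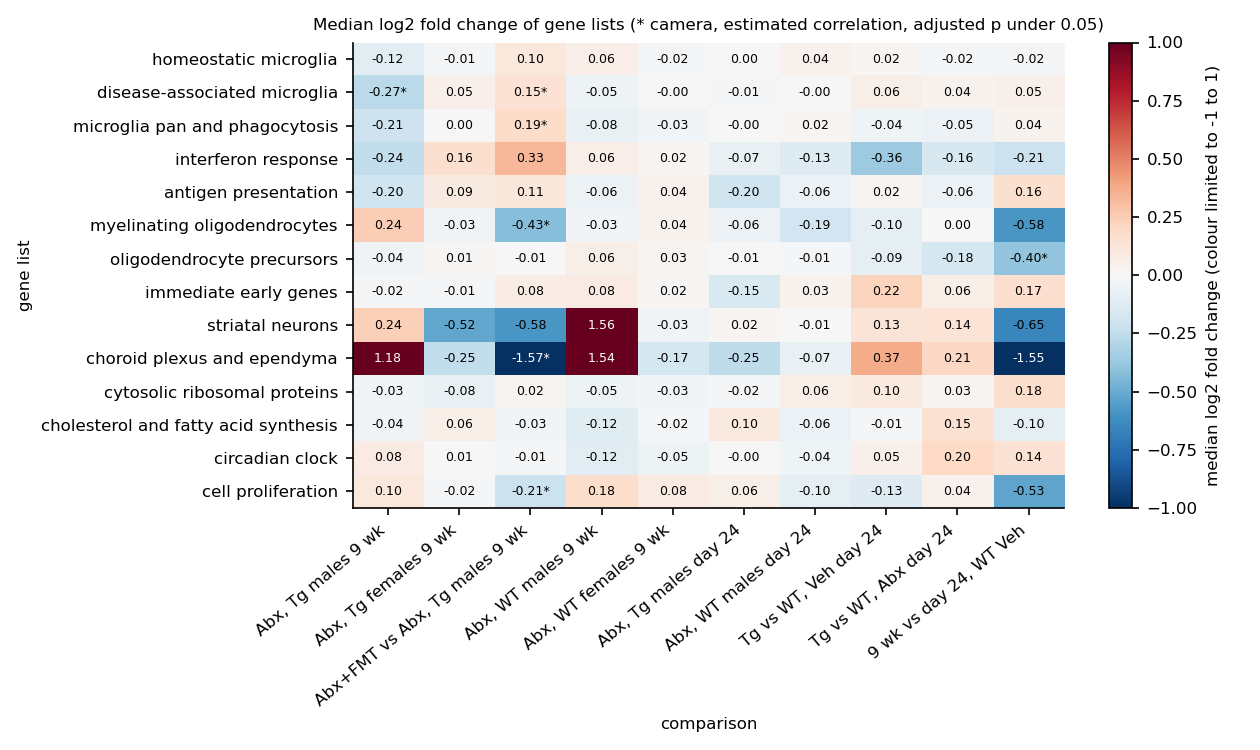
Median log2 change of 14 gene lists in 10 comparisons, with asterisks for lists past the threshold in camera with an estimated correlation and a limited colour range. Striatal genes had a median of 1.56 in antibiotic-treated wild-type males and disease-associated microglia genes a median of -0.268 in antibiotic-treated APPPS1-21 males.

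In wild-type females of 9 weeks no gene changed past the threshold. The genes with the smallest p included the mitochondrial leucine tRNA ligase Lars2 (-0.92). The immediate early gene Fos was at 0.48 (92.4 ± 8.06 against 66.3 ± 17.2 CPM, SD, n = 6 each) and the lipid carrier Apoe at -0.20, all with an adjusted p of 0.999. Camera called 4 lists, the 79 ribosomal protein genes (median -0.03, adjusted p = 0.0221), 24 circadian genes (-0.05, 0.0262), 34 endothelial genes (-0.07, 0.0262) and 29 glucocorticoid response genes (-0.11, 0.0467). Each had 0 genes called over all genes or adjusted over the list alone and adjusted p = 0.937 with an estimated correlation. edgeR called 0 of 17736 genes, with 539 at an unadjusted p under 0.05, and DESeq2 and voom 0.

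The interaction of sex and antibiotics in wild-type mice of 9 weeks also called no gene. The lowest adjusted p was 0.0671 for the zinc finger gene Zfp219 (0.58, SE 0.0991), followed by the glycolysis enzyme Pgk1 (-0.31), the malate dehydrogenase Mdh1 (-0.31) and the basement membrane collagen Col4a1 (0.53); Thy1 was at -0.21 (adjusted p = 0.123). Of 25 striatal genes 0 were called over all genes and 22 were higher in males adjusted over the list alone (median 1.49, adjusted p = 1.51e-11), as were 16 of 28 choroid plexus genes (median 1.85, adjusted p = 2.03e-08). Both lists had 0 called over all genes and adjusted p = 0.649 with an estimated correlation. edgeR called 0 of 17736 genes, with 3203 at an unadjusted p under 0.05, and DESeq2 called 545. Single libraries changed the count, which was 442 without male antibiotic replicate 3, 142 without replicate 2, 71 without replicate 1, 47 without female vehicle replicate 1, 5 without female antibiotic replicate 5 and 2 without female vehicle replicate 5.

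Vehicle-treated wild-type males and females differed in 10 genes, 5 higher and 5 lower in males, with 1016 at an unadjusted p under 0.05. The higher ones included Kdm5d (11.3), Ddx3y (11.42), Eif2s3y (11.78) and Uty (12.31) of the Y chromosome, and the lower ones Xist (-11.95) and the X-linked Eif2s3x (-0.55, adjusted p = 1.98e-08), Kdm5c (-0.42) and Kdm6a (-0.40), which escape X inactivation. The 79 ribosomal protein genes were higher in males with a median of 0.08 (adjusted p = 3.31e-15) and the 28 choroid plexus genes lower with a median of -0.99 (adjusted p = 1.26e-06). Both had 0 called over all genes or adjusted over the list alone and adjusted p = 0.468 with an estimated correlation.

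At day 24, a few days after the last gavage, antibiotics changed no gene past the threshold in wild-type males. The lowest adjusted p was 0.32, shared by the exchange factor Sos1 (-0.15), the thiamine transporter Slc19a2 (-0.27) and the ubiquitin ligase subunit Fbxw7 (0.19). Myelin genes were lower in 31 of 35 members (median -0.19, adjusted p = 9.76e-10), ribosomal protein genes higher (median 0.06, adjusted p = 3.45e-10) and 34 cholesterol genes lower (median -0.06, adjusted p = 0.000146). Each had 0 called over all genes or adjusted over the list alone and adjusted p = 0.665 with an estimated correlation. edgeR called 0 of 17418 genes, with 1390 at an unadjusted p under 0.05, voom 0 and DESeq2 18.

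In APPPS1-21 males of day 24 no gene passed either. The ketone body enzyme Oxct1 was at 0.19 (457 ± 9.42 against 401 ± 12.1 CPM, SD, n = 6 each; adjusted p = 0.0699). The neuronal tubulins Tubb3 and Tubb2a were at 0.18 (0.0711) and 0.20 (0.0743), the microtubule regulator Stmn2 at 0.16 (0.0743) and the sterol enzyme Msmo1 at 0.25 (0.0806). App was at 0.01 and Thy1 at 0.08. Of 34 cholesterol genes 0 passed over all genes, and 14 rose and 1 fell adjusted over the list alone (median 0.10, adjusted p = 1.85e-10; adjusted p = 0.354 with an estimated correlation). Of 45 synaptic genes 0 passed over all genes and 10 rose adjusted over the list alone (median 0.06, adjusted p = 1.9e-09; adjusted p = 0.354 with an estimated correlation). Of 29 fibroblast genes of the meninges 0 passed and 9 fell adjusted over the list alone (median -0.31, adjusted p = 1.12e-06; adjusted p = 0.617 with an estimated correlation). edgeR called 0 of 17418 genes, with 1896 at an unadjusted p under 0.05, voom 48 and DESeq2 136. The count was 23 without vehicle replicate 6, 6 without antibiotic replicate 1, 4 without antibiotic replicate 3 and 1 without vehicle replicates 4 or 5.

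The difference between the genotypes in the antibiotic response at day 24 called 0 of 17418 genes by edgeR, with 1649 at an unadjusted p under 0.05; DESeq2 called 29. Zfp219 was at -0.38, the potassium channel Kcna6 at 0.36 and the laminin Lamc1 at 0.37 (adjusted p = 0.124 for each), the sterol enzyme Nsdhl at 0.37 and the endothelial tight junction gene Cldn5 at -1.04 (adjusted p = 0.2 for both). Of 34 cholesterol genes 33 were higher in APPPS1-21 males in this sense, 0 over all genes, and 14 higher and 1 lower adjusted over the list alone (median 0.17, adjusted p = 9.21e-14; adjusted p = 0.283 with an estimated correlation). The count was 2 without APPPS1-21 vehicle replicate 5 and 1 without wild-type antibiotic replicate 1.

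The genotypes were compared at day 24, where both were in the same library set. In vehicle-treated males Thy1 was higher in APPPS1-21 mice by 1.09 (SE 0.0413, adjusted p = 3.65e-18) and App by 0.35 (SE 0.0302, adjusted p = 9.13e-09). Genes of the oligodendrocyte lineage were among the lower ones. The receptor Gpr17 of differentiating precursors was lower by 0.59 (70.3 ± 8.67 against 106 ± 9.56 CPM, SD, n = 6 each; adjusted p = 8.4e-05) and the protocadherin Pcdh15 by 0.48 (0.000437). The galactolipid enzyme Ugt8a was lower by 0.65 (97.2 ± 19.9 against 153 ± 18.9 CPM, SD, n = 6 each; adjusted p = 0.00407). The immediate early gene Egr4 (1.17, adjusted p = 0.0139), the ferritin chain Fth1 (0.49, 0.00414) and Apoe (0.41, 0.0112) were higher and the nuclear RNA Malat1 lower (-0.74, 0.0259). Of 23 precursor genes 8 were lower and 10 adjusted over the list alone (median -0.09, adjusted p = 0.000138; adjusted p = 0.415 with an estimated correlation). Of 34 endothelial genes 4 were lower and 5 adjusted over the list alone (median -0.16, adjusted p = 0.000138; adjusted p = 0.415 with an estimated correlation). Of 79 ribosomal protein genes 18 were higher and 34 adjusted over the list alone (median 0.10, adjusted p = 2.09e-09; adjusted p = 0.789 with an estimated correlation). In all 940 genes were higher and 774 lower, with 4370 at an unadjusted p under 0.05; without wild-type replicate 6 the count was 1112. With no filter 518 were higher and 666 lower, with RLE scaling 815 and 825, and with GC and length trends removed, an alternative chosen after the data were examined, 868 and 509. GC content and exon length together explained 17.4% of the variance of the changes of the called genes.

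Under antibiotics Thy1 was higher in APPPS1-21 males of day 24 by 1.17 (SE 0.0414, adjusted p = 3.98e-19) and App by 0.34 (SE 0.0301, adjusted p = 2.44e-08). Among the higher genes were those of cholesterol synthesis and of the clock: the sterol carrier Stard4 by 0.42 (adjusted p = 5.41e-06), squalene synthase Fdft1 by 0.32 (3.83e-05), Bhlhe41 by 0.57 (0.00213) and Dbp by 0.59 (0.0222). Cldn5 (-0.83, adjusted p = 0.00706), the vascular growth factor receptor Kdr (-0.67, 0.0181) and the collagen Col1a1 (-1.19, 0.0275) were lower. Of 34 cholesterol genes 12 were higher and 23 adjusted over the list alone (median 0.15, adjusted p = 1.29e-16). Of 24 circadian genes 8 were higher and 2 lower, and 14 higher and 3 lower adjusted over the list alone (median 0.20, adjusted p = 6.1e-06). Of 23 precursor genes 4 were lower and 8 adjusted over the list alone (median -0.18, adjusted p = 3.6e-06). Each of these lists had adjusted p = 0.108 with an estimated correlation. In all 252 genes were higher and 288 lower, with 3173 at an unadjusted p under 0.05. With GC and length trends removed the balance turned to 391 higher and 273 lower. The count moved by over 1.5 times without wild-type replicates 2, 5 or 6 or APPPS1-21 replicates 1, 3, 4 or 5, down to 211 without APPPS1-21 replicate 3; DESeq2 called 873. Over 17418 genes, which are not independent replicates, the genotype differences under antibiotics and under vehicle correlated at r = 0.407 (p = 0.0099, the smallest that 100 reassignments of the labels can give; adjusted p = 0.0495 over 5 correlations of this family).

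Wild-type males were compared between 9 weeks and day 24. Under vehicle, oligodendrocyte precursor and myelin genes were lower at 9 weeks. Gpr17 was lower by 1.27 (44.4 ± 3.45, n = 5, against 107 ± 9.96 CPM, n = 6, SD; adjusted p = 4.22e-13). Ugt8a was lower by 1.33. The proliferation marker Mki67 was lower by 1.26 (5.23e-05), while the cytokine Il33 was higher by 1.29 (4.22e-13). Of 23 precursor genes 16 were lower and 19 adjusted over the list alone (median -0.40, adjusted p = 2.91e-16; adjusted p = 0.000309 with an estimated correlation). Of 35 myelin genes 21 were lower and 1 higher, and 24 lower and 1 higher adjusted over the list alone (median -0.58, adjusted p = 2.01e-20). Of 29 proliferation genes 14 were lower and 1 higher, and 16 lower and 1 higher adjusted over the list alone (median -0.53, adjusted p = 7.62e-06). Both had adjusted p = 0.19 with an estimated correlation. Choroid plexus genes were lower too, 17 of 28 and 23 adjusted over the list alone (median -1.55, adjusted p = 6.14e-10; adjusted p = 0.359 with an estimated correlation). Ribosomal protein genes were higher, 45 of 79 and 57 adjusted over the list alone (median 0.18, adjusted p = 2.01e-20; adjusted p = 0.301 with an estimated correlation). In all 1221 genes were higher and 1552 lower at 9 weeks, with 5167 of 18296 at an unadjusted p under 0.05.

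The antibiotic response of wild-type males differed between the ages. The striatal genes Drd2 (2.84, adjusted p = 0.0309) and Isl1 (3.74) and the choroid plexus gene Clic6 (3.36) responded more upwards at 9 weeks, and Camk2a (-0.25, 0.0139) and Snap25 (-0.34, 0.0165) more downwards. The peroxidasin Pxdn had the lowest adjusted p (0.66, 0.000416). Of 25 striatal genes 11 were higher in this sense and 21 adjusted over the list alone (median 1.70, adjusted p = 5.72e-13; adjusted p = 0.476 with an estimated correlation). Of 28 choroid plexus genes 4 were higher and 13 adjusted over the list alone (median 1.56, adjusted p = 4.75e-08; adjusted p = 0.522 with an estimated correlation). Of 74 oxidative phosphorylation genes 7 were lower and 25 adjusted over the list alone (median -0.14, adjusted p = 2.46e-16; adjusted p = 0.372 with an estimated correlation). In all 347 genes were higher and 273 lower, with 3646 at an unadjusted p under 0.05. The count lay between 188 (without 9-week antibiotic replicate 6) and 1374 (without replicate 3). It moved by over 1.5 times also without 9-week antibiotic replicates 2 or 4, 9-week vehicle replicates 1, 4 or 5, day-24 vehicle replicates 1 or 3 or day-24 antibiotic replicates 3 or 4. It was 252 with no filter (109 higher, 143 lower), 1041 with DESeq2 (500 higher, 541 lower), 295 without the 2 libraries with the highest striatal scores and 1 with the tissue scores as covariates.

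At 9 weeks the male antibiotic response differed between the APPPS1-21 and wild-type cohorts, which are in different library sets. In this sense Clec7a was lower in APPPS1-21 males by 3.01 (SE 0.768, adjusted p = 0.0265) and the lysosomal macrophage marker Cd68 by 0.70 (0.0406), and Isl1 by 3.95 (0.0329). Camk2a (0.21, 0.0265), Snap25 (0.29, 0.0431) and Cpm (0.74, 0.0131) were higher. Ccl3 was at -1.60 (0.38) and App at -0.15 (0.217). In wild-type males Clec7a lay near the floor, at 0.254 ± 0.0867 CPM with antibiotics (SD, n = 6) and 0.165 ± 0.116 CPM with vehicle (SD, n = 5). The wild-type part of its interaction therefore rests on few reads. Of 36 disease-associated microglia genes 3 were lower, and 6 lower and 4 higher adjusted over the list alone (median -0.21, adjusted p = 0.00256; adjusted p = 0.325 with an estimated correlation). Of 25 striatal genes 4 were lower and 18 adjusted over the list alone (median -1.24, adjusted p = 1.44e-08; adjusted p = 0.332 with an estimated correlation). Of 25 neuronal immaturity genes 6 were lower and 10 adjusted over the list alone (median -0.40, adjusted p = 1.08e-06; adjusted p = 0.27 with an estimated correlation). In all 193 genes were higher and 257 lower, with 3250 of 16775 at an unadjusted p under 0.05. RLE scaling moved the balance, to 342 higher and 248 lower, as did DESeq2 (576 and 435). The count lay between 115 (without wild-type antibiotic replicate 6) and 1299 (without replicate 3). It moved by over 1.5 times also without wild-type antibiotic replicates 2 or 5, wild-type vehicle replicate 2, APPPS1-21 vehicle replicates 1, 3 or 5 or APPPS1-21 antibiotic replicates 4, 5 or 6. It was 67 without the 2 libraries with the highest striatal scores (41 higher, 26 lower) and 1 with the tissue scores as covariates. Striatal genes rose more with antibiotics in wild-type than in APPPS1-21 males (medians 1.56 and 0.24). Genotype therefore cannot be told apart here from the library set or from tissue in the dissection.

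In females of 9 weeks the same interaction called no gene. The 25 striatal genes were lower in APPPS1-21 females in this sense (median -0.59, adjusted p = 1.44e-09; adjusted p = 0.745 with an estimated correlation). The endothelial genes were higher (median 0.19, adjusted p = 2.43e-09; adjusted p = 0.427 with an estimated correlation). Both had 0 genes called over all genes or adjusted over the list alone. edgeR and DESeq2 both called 0 of 16775 genes, with 470 at an unadjusted p under 0.05 by edgeR.

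Antibiotic responses of groups that share no library were compared over genes, which are not independent replicates, in 5 pairs, each against 100 reassignments of the treatment labels. Those of APPPS1-21 and wild-type males of 9 weeks correlated at r = 0.206 over 16775 genes (p = 0.0099, the smallest that 100 reassignments can give; adjusted p = 0.0495). The correlation was -0.115 between APPPS1-21 males and females (p = 0.22, adjusted p = 0.55) and 0.00687 between wild-type males and females (p = 0.93). It was 0.0207 between the genotypes at day 24 (permutation p = 0.83) and -0.0217 between wild-type males of both ages (p = 0.76; adjusted p = 0.93 for each of the last 3). Among genes with an average of at least 3 log2 CPM the r of the first pair was 0.218 with a permutation p = 0.22. In both groups of that pair antibiotics went with more choroid plexus transcripts (list medians 1.18 in APPPS1-21 and 1.54 in wild-type males) and striatal transcripts (0.24 and 1.56). A shared response therefore cannot be told apart from shared tissue in the dissection, and a correlation without these genes was not computed.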

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

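In the part below, the tests of the microglial share and the odd library, of GC content and gene length, of earlier maturation, and of the wild-type changes with the scores as covariates were chosen after the results were seen.

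In 7 of 118 groups of values tested for a library far from the others, a library lay beyond the 95% limit for its gap, where chance gives about 1 in 20 groups (5.9 of 118). Vehicle-treated APPPS1-21 male replicate 2 of 9 weeks had 856.8 CPM of Xist (others 0.1615 to 0.41) and 0.138 CPM of Ddx3y (others 101.8 to 111.5). Ddx3y was low in transfer replicate 5 (95.02 CPM, others 108.1 to 114.8) and in vehicle-treated wild-type male replicate 3 of 9 weeks (92.09 CPM, others 104.6 to 106.2). The disease-associated microglia score was low in antibiotic-treated wild-type male replicate 2 of day 24 (-0.107, others -0.00267 to 0.0217), and the striatal score was high in transfer replicate 3 (-0.0605, others -1.04 to -0.751). Thy1 was low in vehicle-treated wild-type replicate 1 of day 24 (605.9 CPM, others 637.1 to 653).

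A difference between groups in the response to antibiotics, tested as an interaction, was called for 3 genes between the sexes of APPPS1-21 mice (Cst7 -3.76, Ccl3 -2.79 and Ccl6 -1.75). It was called for 620 genes between the ages of wild-type males and 450 genes between the genotypes of 9-week males, which are in different library sets. The 3 calls between the sexes were lost without the library with female transcripts. Of 100 splits of the libraries, the real one included, 2 gave as many as the 3 genes (highest other 4), 2 as many as the 620 (highest other 1168) and 4 as many as the 450 (highest other 1224). The share was under 0.05 in each of these, without adjustment over the 19 comparisons, so chance is made less likely but is not excluded. The splits that called 1168 and 1224 genes exceeded the real counts of the comparisons of age and genotype. What those splits share was not tested.

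The first pattern weighed was the fall of the 8 called genes of the microglial lists in antibiotic-treated APPPS1-21 males (median -1.7). A smaller share of microglia would lower the homeostatic list by about as much. Its median over 29 genes was -0.116 (10th percentile -0.317), against -2.2 for the 6 genes that fell by over 1 and -0.487 for the other 2. Over whole lists the medians were -0.268 (disease-associated, 30 of 35 lower), -0.21 (pan-microglial, 33 of 36 lower) and -0.116 (homeostatic, 21 of 29 lower). The 8 genes were selected by their fall in these libraries, which widens the gap, so it cannot decide whether the share changed. Without the library with female transcripts the median ratio of the changes was 0.862 (0.789 to 0.988) and 7 of the 8 passed, with Fcrls at -0.333 (adjusted p = 0.0503). With the striatal and choroid plexus scores as covariates the median ratio was 0.928 (0.768 to 1.03), which argues against striatum and choroid plexus as the source. Other tissue was not tested. All 8 calls ended as errors widened, with Cst7 going from -3.35 (SE 0.533) to -3.11 (SE 0.628). The median SE went from 0.32 to 0.378, and edgeR called 0 genes, with 2118 at an unadjusted p under 0.05. A lower activation of microglia and a smaller share of them are candidate explanations that stay open, as hypotheses found and tested on the same data.

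The second pattern was the set of genes changed in antibiotic-treated wild-type males of 9 weeks, for which GC content and gene length explained 1.73% of the variance, which argues against them. Changes predicted from each gene's relation to the striatal and choroid plexus scores in the 17 wild-type libraries of 9 weeks outside that group correlated with the measured ones at r = 0.474 over 1753 called genes outside the lists (p = 0.012; highest of 1000 reassignments 0.544). The sign was the same in 55.3% of them, and genes are not independent replicates. With the scores as covariates the median ratio of the changes was 0.681 (quartiles 0.371 to 1.01), the median SE went from 0.0747 to 0.104 and edgeR called 0 genes, with 2421 at an unadjusted p under 0.05. More striatum and choroid plexus in the dissected tissue may explain part of the changes and cannot be told apart from an effect of antibiotics, since the scores go with the treatment.

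The third pattern was the genotype difference at day 24 and its relation to age. GC content and gene length explained 17.4% of the variance among the genes called in vehicle-treated males and 3.07% in antibiotic-treated ones, so a bias of library quality cannot be told apart from genotype for part of the former. Earlier maturation of APPPS1-21 pups would give a correlation of genotype and age differences, and r was 0.191 (permutation p = 0.23, adjusted p = 0.24 over 5 correlations) for antibiotic-treated pups against vehicle-treated males and 0.121 (permutation p = 0.099, adjusted p = 0.165) for the other pairing, neither past its test. After removal of the trend of GC content and length r was 0.191 and 0.13, which decides nothing about that trend. Whether the transgenes or the litters account for the difference was not tested.

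Chance was weighed for the other counts with 100 splits each, the real one included. For antibiotics in APPPS1-21 males 1 split gave as many as the real 30 (highest other 24), and for transfer against antibiotics 3 gave as many as 104 (highest other 491). For the APPPS1-21 sex difference 1 gave as many as 335 (highest other 110), for wild-type males 2 as many as 1785 (highest other 2097) and for the wild-type sex difference 2 as many as 10 (highest other 14). For genotype at day 24, 1 split gave as many as 1714 under vehicle (highest other 125) and 1 as many as 540 under antibiotics (highest other 1). For age 1 gave as many as 2773 (highest other 1182). The share was under 0.05 for each of these, again without adjustment over the 19 comparisons, so chance is made less likely but is not excluded. Where the real count was 0, all 100 splits gave as many by construction, with a highest other of 3925 for APPPS1-21 females, 21 for transfer against vehicle, 4 for wild-type females and 4 for the wild-type interaction with sex. It was 198 and 635 for wild-type and APPPS1-21 males of day 24, 618 for their interaction and 1651 for the interaction with genotype in females. Some splits called more genes than the groups did, as in transfer against antibiotics, in wild-type males, in females and for antibiotics at day 24. A structure of the samples other than the groups may account for this, but it was not identified or tested.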

How the results depend on the processing

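Covariates, the fits without the 2 libraries with the highest striatal scores, and the removal of GC and length trends were chosen after the data were examined. No paired analysis was possible because the labels give library numbers and no animal, litter or cage, and the replicate numbers here follow the order of the records.

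With RLE scaling the counts of all 19 comparisons stayed within 1.5 times, as did both with GC and length trends removed. That removal moved the balance of genotype at day 24 from 252 higher and 288 lower to 391 and 273 under antibiotics, and from 940 and 774 to 868 and 509 under vehicle, where RLE scaling gave 815 and 825. The other alternatives moved some counts; beyond the change in genes tested or samples used that each brings, the cause was not tested. With no filter 11 of 19 stayed and 8 moved. They moved to 15 for antibiotics in APPPS1-21 males, 0 for their interaction with sex, 189 for the APPPS1-21 sex difference and 1173 for wild-type males, and to 51 for the wild-type interaction with sex, 20 for APPPS1-21 males of day 24, 3 for the genotype interaction of day 24 and 252 for age by antibiotic. With the comparison's groups alone, which leaves fewer samples for the variance, 9 of 13 stayed and 4 moved, to 83 for APPPS1-21 males, 16 for transfer against antibiotics, 99 for the APPPS1-21 sex difference and 35 for wild-type males.

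DESeq2 left 8 of 19 within 1.5 times and moved 11. It called 245 for APPPS1-21 males, 35 for their interaction with sex, 225 for transfer against antibiotics, 828 for the APPPS1-21 sex difference and 545 for the wild-type interaction with sex. At day 24 it called 18 and 136 for wild-type and APPPS1-21 males, 29 for their interaction and 873 for genotype under antibiotics. It called 1041 for age by antibiotic and 1011 for genotype by antibiotic in males. Voom moved 3 of 8, to 983 for APPPS1-21 males, 235 for transfer against antibiotics and 48 for APPPS1-21 males of day 24. With 1 surrogate variable 5 of 11 moved, to 246, 167, 772, 2 and 1 for APPPS1-21 males, transfer against antibiotics, wild-type males of 9 weeks and day 24 and the genotype interaction of day 24. In the wild-type cohort of 9 weeks that variable correlated with the striatal score within groups at -0.807.

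With the scores as covariates 7 of 14 moved, to 0 for APPPS1-21 males (2118 at an unadjusted p under 0.05), their interaction with sex (1295), transfer against antibiotics (765) and wild-type males (2421). They moved to 1 for the genotype interaction of day 24, age by antibiotic and genotype by antibiotic in males. Without the 2 libraries with the highest striatal scores, 4 of 4 moved, to 1074 for wild-type males, 55 for their interaction with sex, 295 for age by antibiotic and 67 for genotype by antibiotic in males.

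With single libraries left out the counts ranged from 7 to 159 for APPPS1-21 males, 0 to 0 for females, 0 to 13 for their interaction, 32 to 218 for transfer against antibiotics, 0 to 1 for transfer against vehicle and 37 to 786 for the sex difference. They ranged from 758 to 2671 for wild-type males, 0 to 0 for females, 0 to 442 for their interaction and 8 to 11 for the sex difference. At day 24 they ranged from 0 to 0 in wild-type males, 0 to 23 in APPPS1-21 males, 0 to 2 for the interaction, 1112 to 1603 for genotype under vehicle and 211 to 750 under antibiotics. They ranged from 188 to 1374 for age by antibiotic, 2139 to 2679 for age, and 115 to 1299 and 0 to 0 for genotype by antibiotic in males and females.

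Of 8191 alternatives of 414 called and named genes 6212 stayed past the threshold, 1973 no longer passed and 6 changed sign. All 6 did so with the scores as covariates: Clic6 in transfer against antibiotics (0.23), Clic6, Isl1 and Dlk1 in wild-type males (-0.45, -0.092 and -0.12), and Ano2 and Six3 in age by antibiotic (-0.13 and -0.017). The adjusted scores hold choroid plexus and striatal genes, and the cause was not tested further. Among genes with an average of at least 3 log2 CPM the agreement of antibiotic effects was -0.0568 between wild-type males and females, -0.0885 between the genotypes of day 24 and 0.0497 between the ages. Each was of opposite sign to the value over all genes and none passed its test. It was 0.218 between the genotypes of 9-week males, no longer past its permutation test (p = 0.22). The cause was not tested. Depth was higher in APPPS1-21 libraries of 9 weeks (51.9 to 59.8 M counts) than in the others (23.4 to 27 M).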

Other observations

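In the part below, the test with the neuron score removed was chosen after the result was seen.

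In antibiotic-treated APPPS1-21 males of 9 weeks, camera called further lists with the preset correlation but not with an estimated one. Of 37 heat shock and unfolded protein genes 0 passed over all genes and 3 rose adjusted over the list alone (median 0.15, adjusted p = 6.99e-06; adjusted p = 0.385 with an estimated correlation), with the chaperone Hspa5 at 0.55 (SE 0.174, adjusted p = 0.138). Of 30 glucocorticoid response genes 0 passed and 3 rose adjusted over the list alone (median 0.16, adjusted p = 0.00204; adjusted p = 0.671 with an estimated correlation), with Fkbp5, a chaperone of the glucocorticoid receptor, at 0.66 (SE 0.256, adjusted p = 0.22). Of 20 antigen presentation genes 0 passed and 2 fell adjusted over the list alone (median -0.20, adjusted p = 1.26e-05; adjusted p = 0.284 with an estimated correlation), with the class I light chain B2m at -0.27 (SE 0.0719, adjusted p = 0.0887).

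At day 24, 5 of 33 immediate early genes were higher in vehicle-treated APPPS1-21 males than in wild-type males, and 5 adjusted over the list alone (median 0.22, adjusted p = 0.0039; adjusted p = 0.75 with an estimated correlation). Of 33 interferon response genes 3 were lower and 1 higher, and 8 lower and 2 higher adjusted over the list alone (median -0.36, adjusted p = 0.00489; adjusted p = 0.75 with an estimated correlation).

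The lower App level of antibiotic-treated APPPS1-21 males (-0.225) was tested for a relation to the microglial genes. Over the 30 APPPS1-21 libraries of 9 weeks, deviations of App from its group mean correlated with those of the disease-associated microglia score at r = 0.599 (permutation p = 0.0036; rho = 0.599, permutation p = 0.00293; r = 0.605 without the 2 farthest libraries). With the excitatory neuron score removed r was 0.603, which argues against the share of neurons as its source. With the striatal and choroid plexus scores as covariates the ratio of the App changes was 0.964, which argues against striatum and choroid plexus as the source, although the App call ended (-0.217, adjusted p = 0.13). Other tissue was not tested. App transcripts may therefore vary together with microglial activation within groups, as a hypothesis. A change of the Thy1 promoter that drives the transgenes stays open: Thy1 was at -0.25 in these males (adjusted p = 0.117) and at -0.20 in wild-type males, where all calls ended with the scores as covariates. In the APPPS1-21 males Thy1 was at -0.248 with the scores as covariates (edgeR adjusted p = 0.22).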
